A study of Mus musculus with 14 samples.

How the data were processed

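The data are bulk RNA-seq libraries from mouse embryonic kidney. Per the labels' protocols, kidneys at embryonic day 13.5 were dissociated with enzymes, and cells of the ureteric bud, the epithelial outgrowth that forms the collecting ducts, were isolated by fluorescence-activated sorting for GFP. The GFP comes from the Hoxb7-Cre transgene, which also deletes floxed alleles in that lineage, per the series' design text. Complementary DNA was made with a SMARTer Ultra Low RNA kit, which amplifies full-length copies from small amounts of RNA. That kit does not mark the strand, so reads of a gene and of an antisense neighbour cannot be told apart. The 14 libraries were grouped by their titles and genotype labels into 5 Cep120 KO libraries (replicates 2, 4, 5, 6 and 7), 3 controls of the Cep120 line, 3 Pkd1 KO libraries and 3 controls of the Pkd1 line. The controls carry the genotype label WT, while their titles mark them as heterozygous.

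The values analysed are estimated counts of reads per gene, which the authors deposited without normalization; the step that made the estimates is not stated. Between 88.4 and 91.6% of the values in a library are whole numbers, and all were rounded before testing, which changed no library total by more than 0.00034%. The submitters' processing notes name DRAGEN and the mm9 build, with no version or role. The aligner settings, the annotation release and the treatment of reads that fit several places are not given in the sources used here. The deposited log2 values are log2 of CPM plus a small constant added by the authors, and they served for an alternative test. Of 55774 lines in the count table, 287 repeated a gene under another identifier and were dropped, which left 55487 genes. For 55141 of them a length, GC content and GRCm38 position were taken from the GENCODE M21 annotation by Ensembl identifier. Coordinates in the text are from that annotation, not from the build named by the submitters. Total counts ran from 11347657 to 27967596 per library. The counts carry no molecular identifiers, so copies made by amplification cannot be removed.

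Tests used R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr at a minimum count of 10, which left 16876 genes, and libraries were scaled by TMM. The filtered counts of all 14 libraries entered a quasi-likelihood model with 4 group means and 10 residual degrees of freedom. Contrasts compared Cep120 KO with its controls, Pkd1 KO with its controls, the difference between those effects, and the control groups with each other. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2 scale with their standard error (SE), and CPM values are scaled by TMM.

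The design, the alternatives and the gene lists were fixed before the data were examined. The 26 lists cover p53 target genes, the mitotic surveillance pathway, apoptosis regulators, mitosis genes, DNA replication genes, centriole and centrosome components, primary cilium components, cystic kidney disease genes, the Hedgehog pathway, ureteric bud tip markers, ureteric trunk and collecting duct markers, ureteric lineage and epithelial identity, Wnt/beta-catenin target genes, Hippo/YAP target genes, profibrotic and inflammatory factors, interferon-stimulated genes, the integrated stress response, glycolysis genes, immediate early and heat shock genes, nephron progenitor markers, nascent nephron markers, stromal markers, endothelial markers, erythroid markers, macrophage and leukocyte markers, and neural and neural crest markers. Each list was tested with camera, which asks whether a list moves against all other genes, at a preset inter-gene correlation of 0.01 and with Benjamini-Hochberg adjustment over the 26 lists. The list tests were repeated with the correlation estimated from the data and with fry, which asks whether the genes of a list move on balance in a single direction. A list's median per library is taken over log2 CPM (prior count 2) as the difference from the mean of the Cep120-line controls.

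The genes named were set by a rule. It takes Cep120 and Pkd1 in every comparison. For each KO against its controls it takes up to 10 genes with the highest and up to 10 with the lowest fold change among called protein-coding genes with a mean CPM of at least 5 and every KO library on the same side of every control, leaving out predicted genes, Xist and Y-linked genes. From each list it takes up to 3 called members with the smallest adjusted p, or the member with the smallest p where none was called. For the controls it takes up to 3 genes in each direction. Other genes are named only where the text says that they were chosen after their values were seen.

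The alternatives were DESeq2 size factors (edgeR's RLE), no low-count filter, a separate fit of the groups compared, the Wald test of DESeq2 1.42.0, limma 3.58.1 with voom and sample quality weights, limma-trend on the deposited log2 values, all 6 controls pooled, a set of gene classes left out, the replicate number as a block, and each library left out in turn. After the data were seen, fits with Cep120 KO library 2 alone, without libraries 6 and 7, without libraries 4 and 5, with libraries 4 and 5 summed, and with offsets for transcript length and GC content were added.

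The model was tested on simulated counts, drawn from the mean of each gene over all libraries and from the real library sizes. Genes were drawn independently, without differences between library sets, length or GC trends, or correlation between genes. The shares below therefore do not measure error rates where the real libraries hold such structure. For the Cep120 comparison, 31% of the 100 genes changed 2-fold and 90% of the 100 changed 4-fold were recovered among 16370 genes, with 0.043% of unchanged genes called. The list that had been shifted was called, and so was 1 list that had not. For the Pkd1 comparison, 9% of the 100 genes changed 2-fold and 75% of the 100 changed 4-fold were recovered among 16336 genes, with 0.012% of unchanged genes called, and the shifted list was called with 0 others.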

Results

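The series asks which genes and pathways change in the ureteric bud of the embryonic mouse kidney when centrosomes are lost. Cep120 is a centriolar protein needed to build centrioles, and Pkd1 encodes polycystin-1, the protein most often mutated in dominant polycystic kidney disease. RNA was sequenced from GFP-sorted ureteric bud cells of embryonic kidneys. There were 5 libraries labelled Cep120 KO (libraries 2, 4, 5, 6 and 7), 3 controls of that line (controls 1, 2 and 3), 3 libraries labelled Pkd1 KO and 3 controls of the Pkd1 line. Total counts were 16293837 to 23761736 in the libraries labelled Cep120 KO, 18200490 to 27475901 in their controls, 11347657 to 27967596 in Pkd1 KO and 22061677 to 23181220 in the Pkd1-line controls. The labels do not say whether replicates came from separate embryos, litters or pools, so p-values measure the spread between these libraries, which may be technical.

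Cep120 transcripts were not lower in the libraries labelled Cep120 KO. The gene (ENSMUSG00000048799, chromosome 18, 53681723 to 53744608, GRCm38, GENCODE M21) was read at 7.87, 19.5, 21.2, 13.1 and 16.5 CPM in libraries 2, 4, 5, 6 and 7, from 120, 366, 517, 365 and 517 reads. Controls 1, 2 and 3 had 10.6, 6.41 and 9.45 CPM, from 181, 156 and 154 reads. The log2 difference of 0.83 (SE 0.31) missed the threshold with edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.0832). Without library 2 it was 0.99 and passed (edgeR adjusted p = 0.0088). It also passed with DESeq2 at 0.80 (adjusted p = 0.0461), limma-voom at 1.27 (adjusted p = 0.000353) and limma-trend at 1.16 (adjusted p = 0.041), where the median of all genes was 0.45. It was 0.47 with length and GC offsets (edgeR adjusted p = 0.24), 0.51 without libraries 4 and 5 (0.263) and -0.14 with library 2 alone (0.906). The labels do not say which exons were deleted, and reads from the rest of the gene would remain, so these reads check the label only in part. Pkd1 (ENSMUSG00000032855, chromosome 17, 24549834 to 24596508, GRCm38) had 2.68, 2.39 and 2.42 CPM in the Pkd1 KO libraries, from 29, 63 and 35 reads, against 4.60, 3.34 and 3.84 CPM in their controls, from 98, 73 and 85 reads. Each KO library lay below each control. The log2 difference of -0.65 (SE 0.43) did not pass over all genes tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1). That SE draws on the spread of all groups, the libraries labelled Cep120 KO included. In a separate fit of the Pkd1 line the difference was again -0.65, with an SE of 0.32 (edgeR adjusted p = 0.929). In the plot of the targeted genes, libraries 4 to 7 also stand above all others in Pkd1.

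**Figure D1:**
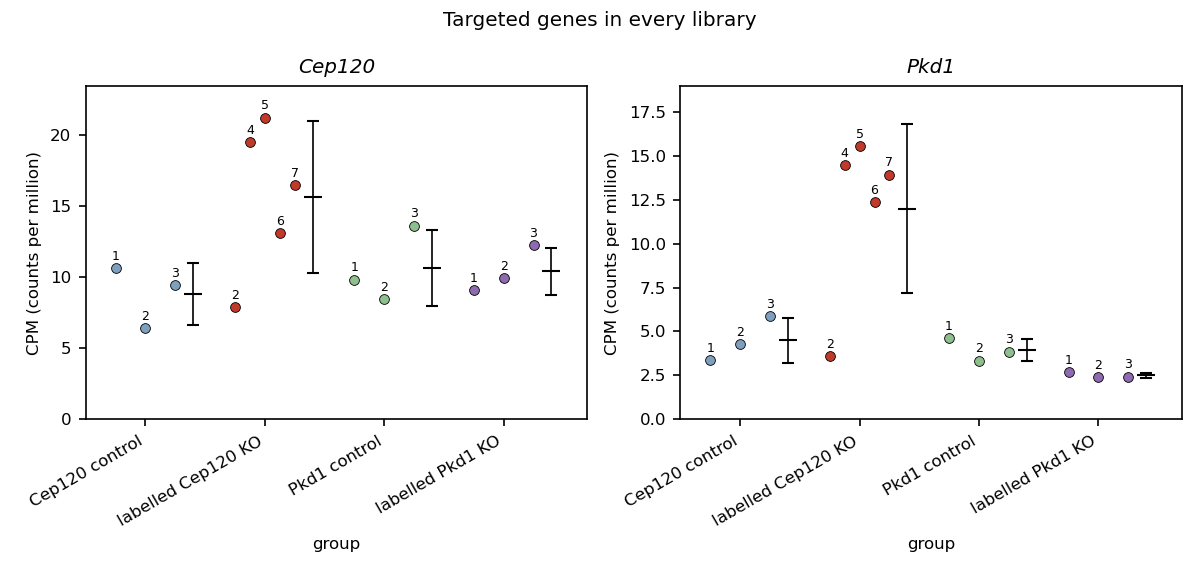
CPM values of Cep120 and Pkd1 (vertical axes) in each of the 14 libraries by group, with replicate numbers; black bars give the group mean and SD. Cep120 lies between 13.1 and 21.2 CPM in libraries 4 to 7 and at 7.87 CPM in library 2 of the group labelled Cep120 KO, against 6.41 to 10.6 CPM in its controls.

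Libraries 4 to 7 of the group labelled Cep120 KO lay apart from the other 10 libraries in length trend, GC trend and TMM factor, measures that do not name a pathway. For length and GC content the reference was the mean of the controls of both lines, which are among the other 10. Genes in the tenth with the longest transcripts lay above those in the tenth with the shortest by 0.71 to 0.81 (log2) in libraries 4 to 7. In the other 10 that difference was -0.22 to 0.36. The same difference for GC content was 0.34 to 1.16 against -0.12 to 0.11, and TMM factors were 1.15 to 1.32 against 0.862 to 0.966. Mitochondrially encoded genes took 2.15 to 3.61% of counts in libraries 4 to 7, 4.69% in library 2 and 3.36 to 5.69% in the libraries of the other groups. Nephron progenitor transcripts were high in libraries 6 and 7, with Six2 at 127 and 86.1 CPM against at most 1.53 CPM in each of the other 12. The labels give no batch, and libraries 4 to 7 belong to 1 group, so a library set and the genotype cannot be told apart for them.

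In the libraries labelled Cep120 KO, lists of p53 target genes, centrosome genes, Hippo/YAP targets and immediate early genes were higher than in the controls with camera at its preset correlation. With an estimated correlation none of the 26 lists passed (camera, smallest adjusted p = 0.183). Among the genes named by the rule, the largest rises were in Six2, a nephron progenitor transcription factor (log2 fold change 5.98, SE 1.82), the heat shock gene Hspa1a (5.74, SE 1.37), the homeobox gene Meis3 (5.38, SE 1.61) and the stress-induced transcription factor Atf3 (5.02, SE 1.03). Pakap, Xylt1, the cartilage collagen gene Col2a1, Ubtd1, the centriolar appendage gene Fbf1 and Csf2ra rose by 4.83, 4.08, 3.97, 3.57, 3.55 and 3.50. Six2 was at 43.3 ± 59.6 CPM (SD, n = 5) against 0.686 ± 0.0625 (n = 3), a spread that comes from libraries 6 and 7. Of these 10 genes all but Atf3 were highest in libraries 6 and 7. Meis3 had 39.0 and 31.4 CPM there against 1.07 to 1.31 CPM in libraries 2, 4 and 5, and Csf2ra 42.4 and 42.6 against 3.67 to 4.27. Pakap had 26.6 and 26.7 CPM against 1.18 to 3.57, and Xylt1 16.3 and 16.4 against 1.44 to 3.08. The platelet chemokine gene Pf4 showed the largest fall (-6.93, SE 1.58), from 113 ± 163 CPM (n = 3) to 0.851 ± 1.13 (n = 5). Its controls 1, 2 and 3 had 35.3, 300 and 4.24 CPM, so control 2 carries most of that mean. The histone gene H2ac7, Tmed6, Akr1c19, the leukocyte actin regulator Coro1a, Tuba4a, Cela1, the arginase gene Arg2, Car8 and H2-DMb2 had log2 fold changes of -1.95, -1.83, -1.79, -1.70, -1.69, -1.64, -1.59, -1.57 and -1.55. H2ac7 belongs to a histone family of near-identical sequence, and its reads are uncertain.

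Of 16876 genes, 2475 were called between the libraries labelled Cep120 KO and their controls by edgeR's quasi-likelihood test, 1418 higher and 1057 lower, with adjusted p (Benjamini-Hochberg) from 0.0118 upward. Of these, 1153 were higher and 319 lower by at least 2-fold. All 5 libraries lay on the same side of all 3 controls for 1477 of the called genes and for 15.2% of all genes tested, where chance gives 3.6%. The count rested on few libraries: it was 5719 without library 2, 1557 without library 4, 1296 without library 5, 314 without library 6 and 8 without library 7. It was 2 without control 1 (Coro1a and Ndor1), 6 without control 2 and 3 without control 3 (Coro1a, Cep162 and Gp9), genes chosen after their values were seen, and 1303 to 1441 without any library of the Pkd1 line. A fit of these 8 libraries alone with edgeR called 0 genes (4081 at an unadjusted p under 0.05, smallest adjusted p = 0.133), limma-voom called 6665 and DESeq2 4199. The limma-voom quality weights were 3.85 and 3.34 for libraries 4 and 5 and 0.125 to 0.162 for libraries 2, 6 and 7. Libraries 4 and 5 differed by 3.13 times sampling noise, against at least 5.98 for any other pair, and the labels do not say whether they are separate replicates. With these summed as 1 sample, 1400 genes were called. Fits chosen after the data were seen gave 1028 genes without libraries 6 and 7 (776 of the 2475 among them), 1488 with length and GC offsets (1329 shared). The fit called 5 genes with library 2 as the only KO library (Eda2r, Cd151, Fam177a, Tmed9 and the pseudogene Gm13370, chosen after their values were seen). In this and every later fit with library 2 alone, that library has no spread of its own and is assumed to vary like the other groups. Of the 20 genes named above, Coro1a alone stayed under 0.05 with any library left out. The other 19 reached edgeR adjusted p up to 0.162, 0.135, 0.138 and 0.0886 without control 1, 2 or 3 or library 7. They reached up to 0.0539, 0.0589 and 0.0745 without library 4, 5 or 6, and up to 0.0627 without any library of the Pkd1 line.

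**Figure D2:**
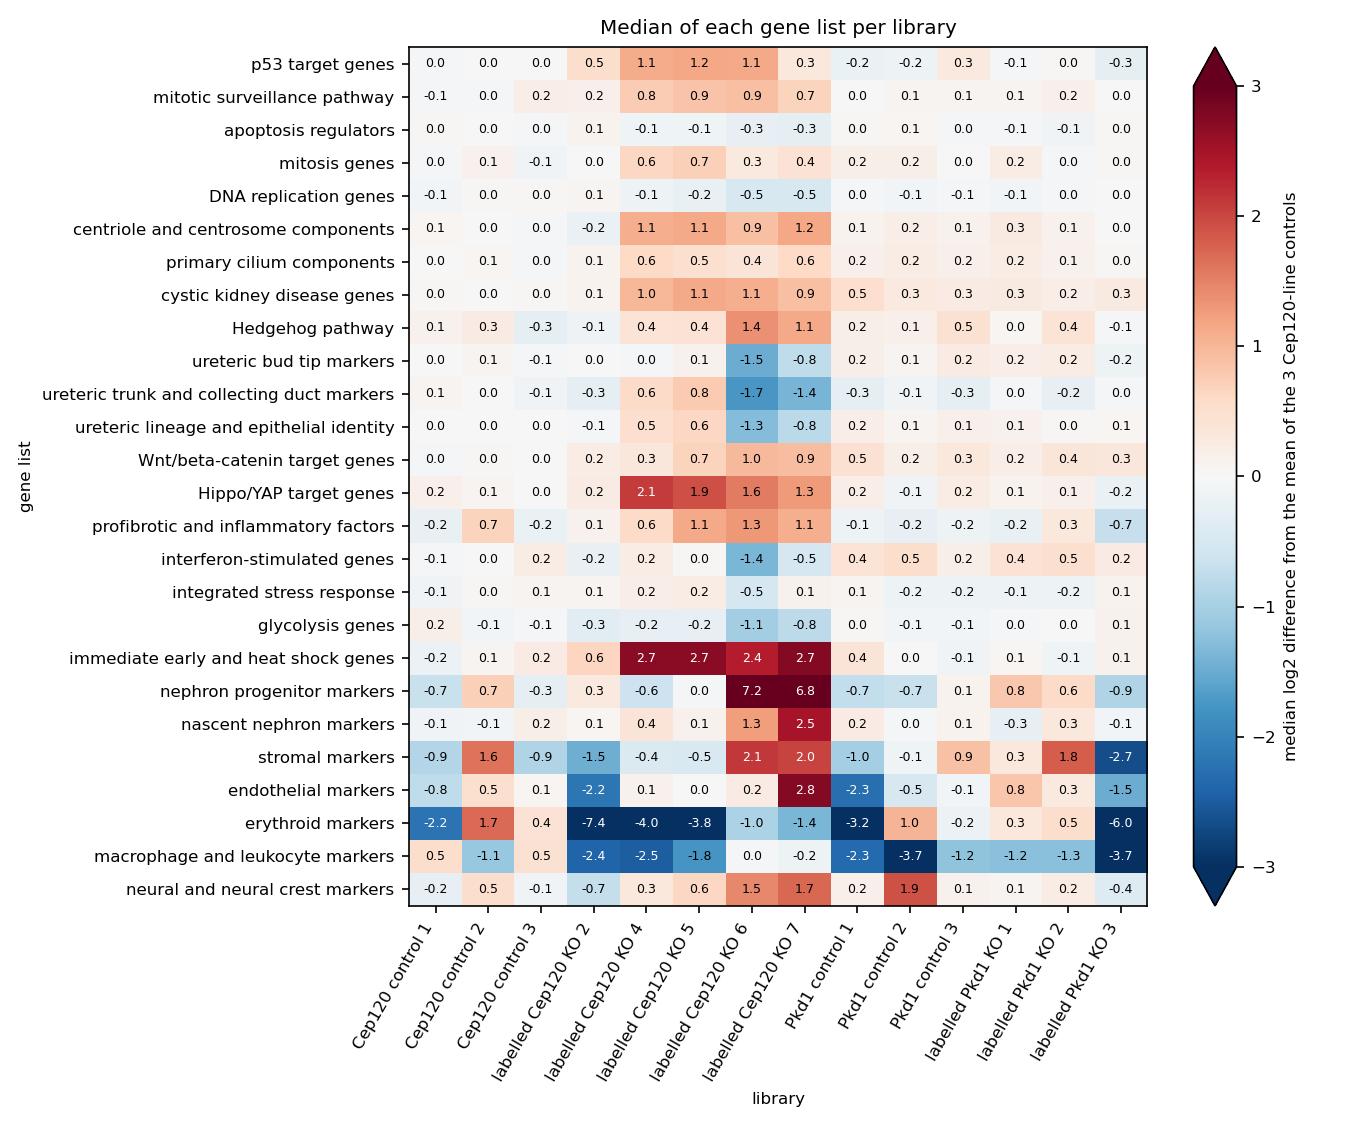
Median log2 difference of each of the 26 gene lists (vertical axis) in each library (horizontal axis) from the mean of the 3 Cep120-line controls, with colours limited at 3 in each direction. Immediate early and heat shock genes stand at 2.36 to 2.75 in libraries 4 to 7, and nephron progenitor markers at 7.18 and 6.79 in libraries 6 and 7.

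Genes that p53 activates after damage or prolonged mitosis were higher in the libraries labelled Cep120 KO. Plk2, a kinase gene induced by p53, rose from 12.6 ± 1.80 CPM (n = 3) to 76.7 ± 20.9 (n = 5), and had 40.1 CPM in library 2 (log2 fold change 2.60, SE 0.33, edgeR quasi-likelihood adjusted p = 0.0118). The nuclease gene Aen rose by 0.98 (SE 0.18) and the microtubule regulator Psrc1 by 1.37 (SE 0.26). Of 30 p53 target genes, 14 were called higher and 0 lower over all genes, and 16 were higher when adjusted over the list alone. The list passed camera (adjusted p = 1.27e-06, median log2 fold change 1.05; adjusted p = 0.183 with an estimated correlation). Its median was 0.53 in library 2, 1.11, 1.16, 1.13 and 0.33 in libraries 4 to 7, and at most 0.29 in the other 9 libraries.

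The mitotic surveillance pathway, through which 53BP1 and USP28 activate p53 when centrosomes are missing, had 4 of 8 genes higher and 0 lower, with the same 4 and 0 when adjusted over the list alone. Trp53bp1 rose by 1.04 (SE 0.26), Pidd1 by 0.93 (SE 0.23) and the cell cycle inhibitor Cdkn1a by 0.99 (SE 0.26), from 41.7 ± 1.87 CPM (n = 3) to 83.0 ± 24.0 (n = 5). The list passed camera (adjusted p = 0.0209, median 0.81; adjusted p = 0.372 with an estimated correlation), and missed the threshold without control 2 (camera adjusted p = 0.0574), without libraries 4 and 5 (0.0752) and with library 2 alone (0.116). Cdkn1a and Mdm2 are also in the p53 list. Apoptosis regulators did not pass camera (adjusted p = 0.342, median -0.23, mean 0.09), with 1 of 16 higher and 1 lower over all genes and 2 and 1 when adjusted over the list alone. The death-promoting gene Bcl2l11 rose by 1.68 (SE 0.41) and cytochrome c gene Cycs fell by 1.03 on the log2 scale (SE 0.27). Of the 8 genes named from these 3 lists, 1, 2, 5 and 7 were no longer called without library 4, 5, 6 and 7 (edgeR adjusted p up to 0.0504, 0.0514, 0.0545 and 0.0597). Without control 1, 2 and 3, 8, 7 and 8 of them were lost (up to 0.123, 0.102 and 0.101).

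**Figure D3:**
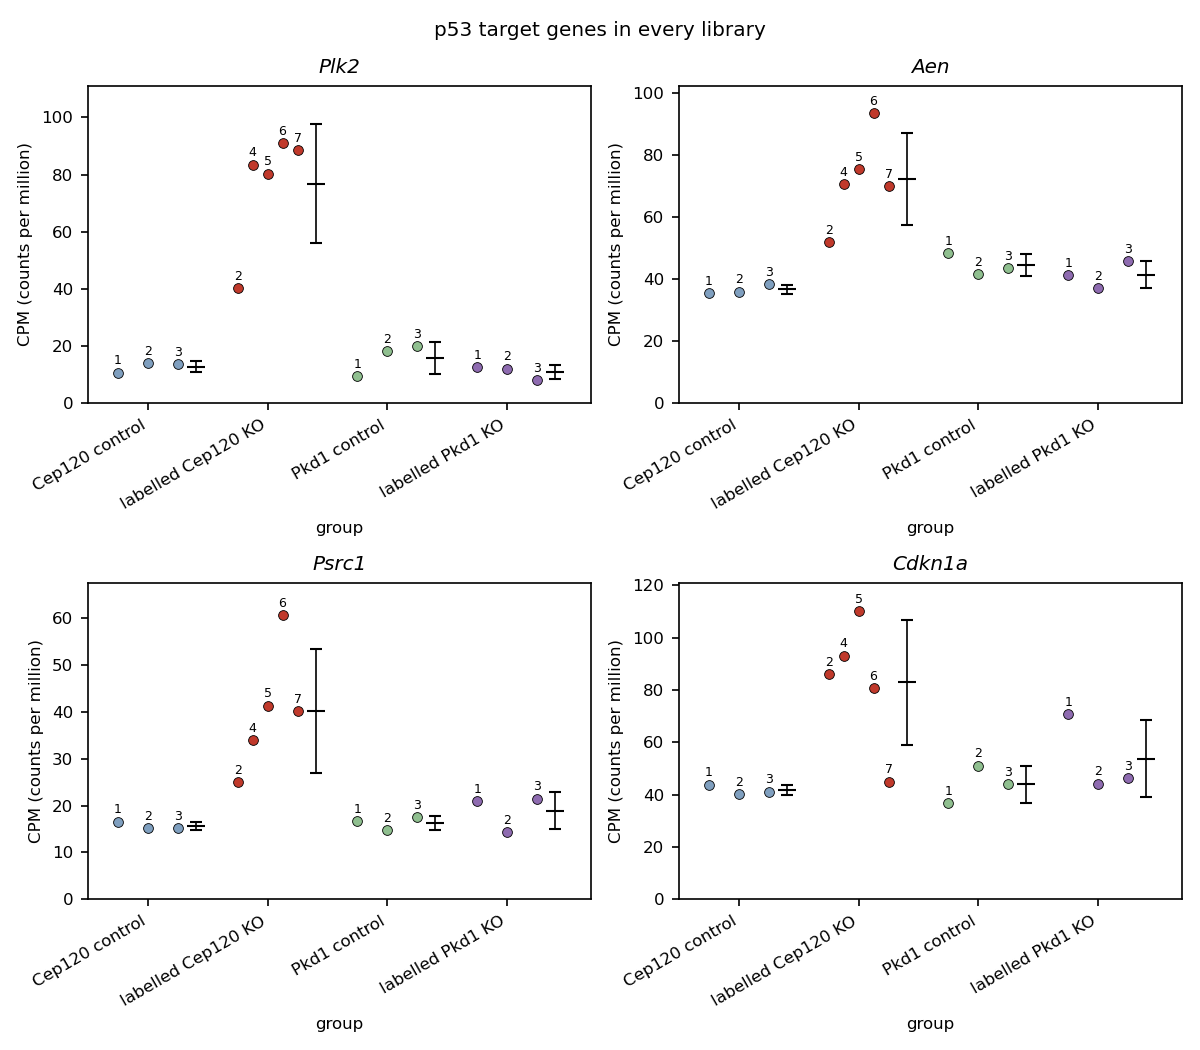
CPM values (vertical axes) of 4 genes of the p53 list in each library by group, with replicate numbers; black bars give the group mean and SD. Plk2 lies at 40.1 CPM in library 2 and at 80.3 to 91.0 CPM in libraries 4 to 7 of the group labelled Cep120 KO, and at no more than 19.7 CPM in the other 9 libraries.

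Mitosis genes were higher and DNA replication genes slightly lower. The proliferation marker Mki67 rose by 3.31 (SE 0.73), the kinetochore motor Cenpe by 3.01 (SE 0.69) and topoisomerase Top2a by 0.98 (SE 0.24); Top2a had 125 CPM in library 2 against 124 ± 10.7 (n = 3) in controls. Of 25 mitosis genes, 8 were higher and 1 lower, and the same counts held when adjusted over the list alone (camera adjusted p = 0.0284, median 0.50; adjusted p = 0.424 with an estimated correlation). Of 25 DNA replication genes, 0 were higher and 1 lower, and 0 when adjusted over the list alone (camera adjusted p = 0.0453, median -0.14; adjusted p = 0.604 with an estimated correlation). The lower gene was Rfc4, a clamp loader subunit (-0.64, SE 0.17). Mki67 and Cenpe have long transcripts, and long transcripts were higher in libraries 4 to 7. With library 2 alone, whose spread is taken from the other groups, DNA replication genes turned upward (camera adjusted p = 0.00226), Mki67 had a log2 fold change of -0.78 and the mitosis list was at 0.847. The mitosis list missed 0.05 without library 4 (0.0502), control 1 (0.0549) or control 3 (0.0832), without libraries 4 and 5 (0.137) and with these summed (0.0505). The replication list missed it without library 4, 5, 6 or 7 or control 2 or 3 (0.0502, 0.0696, 0.107, 0.101, 0.0651 and 0.0765), without libraries 6 and 7 (0.385) or 4 and 5 (0.137), with these summed (0.0575), with length and GC offsets (0.0553) and with fry (0.154). The 4 named genes reached edgeR adjusted p of 0.0635, 0.138, 0.0933 and 0.0949 without library 7 and controls 1, 2 and 3, and up to 0.0542, 0.0571 and 0.058 without library 4, 5 or 6. Rfc4 alone was also lost without 5 of the 6 Pkd1-line libraries, at up to 0.0511.

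Centrosome, cilium and cystic disease genes were higher as groups. Library 2 stayed near the controls in the medians of cilium (0.10) and cystic disease genes (0.11), and lay below them for centriole components (-0.20). Of 24 centriole and centrosome components, 9 were higher and 2 lower (13 and 2 when adjusted over the list alone), with Cep135 up by 3.15 (SE 0.73), the pericentriolar scaffold gene Pcnt by 2.51 (SE 0.64) and the centriole cap gene Ccp110 by 1.71 (SE 0.44). The list passed camera (adjusted p = 0.00225, median 0.85; adjusted p = 0.424 with an estimated correlation), and its median was -0.20 in library 2 and 0.91 to 1.16 in libraries 4 to 7. Of 31 primary cilium components, 6 were higher and 2 lower (7 and 2 when adjusted over the list alone; camera adjusted p = 0.0145, median 0.53; adjusted p = 0.372 with an estimated correlation). Tctn1 rose by 1.22 (SE 0.33), the ciliary motor Kif3a by 1.20 (SE 0.32) and the BBSome gene Bbs4 from 4.89 ± 1.38 CPM (n = 3) to 19.6 ± 7.75 (n = 5). Of 12 cystic kidney disease genes, 3 were higher and 0 lower (7 and 0 when adjusted over the list alone; camera adjusted p = 0.00412, median 0.85; adjusted p = 0.372 with an estimated correlation). They were Pkd1 (1.42, SE 0.39, adjusted p = 0.0345 with edgeR), Bicc1 (1.31, SE 0.35) and Dzip1l (1.32, SE 0.37). The Hedgehog pathway did not pass (camera adjusted p = 0.288, median 0.84), with 1 of 12 genes, the co-receptor Boc, higher (1.92, SE 0.57) and 0 lower, and 0 when adjusted over the list alone. With library 2 as the only KO library, and its spread taken from the other groups, the centriole list turned downward (camera adjusted p = 0.0354), the log2 fold changes of Pkd1, Ccp110 and Kif3a were -0.30, -0.36 and -0.25. The cilium and cystic lists were at 0.834 and 0.418 in that fit, and without libraries 4 and 5 they were at 0.0886 and 0.0644. All 10 named genes were no longer called without library 7 or control 1, 2 or 3 (edgeR adjusted p up to 0.0825, 0.152, 0.122 and 0.13). Of these, 4, 6 and 9 were lost without library 4, 5 and 6 (up to 0.0556, 0.0593 and 0.0746). Pkd1, Dzip1l and Boc were also lost without some of the 6 Pkd1-line libraries, at up to 0.0582.

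Immediate early, heat shock and Hippo/YAP target genes were the other groups that rose. Of 16 immediate early and heat shock genes, which tissue dissociation also induces, 13 were higher and 0 lower (15 and 0 when adjusted over the list alone; camera adjusted p = 3.49e-09, median 2.92; adjusted p = 0.28 with an estimated correlation). Egr1 rose by 3.23 (SE 0.62), the phosphatase gene Dusp1 by 2.65 (SE 0.52) and Jund by 1.46 (SE 0.28), and the list median was 0.64 in library 2 and 2.36 to 2.75 in libraries 4 to 7. Of 14 Hippo/YAP target genes, 5 were higher and 0 lower (8 and 0 when adjusted over the list alone; camera adjusted p = 4.39e-05, median 1.25; adjusted p = 0.372 with an estimated correlation). Ccn1 rose by 3.14 (SE 0.58), Amotl1 by 2.65 (SE 0.50) and Amotl2 by 1.86 (SE 0.38). Their median was 0.23 in library 2 and 1.28 to 2.09 in libraries 4 to 7, and with library 2 alone the list was at a camera adjusted p of 0.278 and Egr1 at a log2 fold change of -0.15. Glycolysis genes were lower, with 0 of 19 gene records higher and 4 lower (0 and 7 when adjusted over the list alone; camera adjusted p = 0.00187, median -0.50; adjusted p = 0.372 with an estimated correlation). Ldha fell by 1.28, Pgk1 by 0.93 and Gapdh by 0.59 on the log2 scale (SE 0.25, 0.22 and 0.15).

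Other signalling lists did not pass. Of 14 Wnt/beta-catenin target genes, 3 were higher and 0 lower (4 and 0 when adjusted over the list alone; camera adjusted p = 0.18, median 0.76): Myc (0.86, SE 0.25), Ccnd1 (0.66, SE 0.21) and Lef1 (0.96, SE 0.30). Myc had a log2 fold change of -0.07 with library 2 alone. The list passed with fry (adjusted p = 0.00356), without libraries 6 and 7 (camera adjusted p = 0.0244) and with library 2 alone (0.0224, spread taken from the other groups). Of 13 profibrotic and inflammatory factors, 1 was higher, the growth factor Pdgfa (1.21, SE 0.24), and 0 lower, with the same counts when adjusted over the list alone (camera adjusted p = 0.166, median 0.46; fry adjusted p = 0.047). Of 14 interferon-stimulated genes, 0 were higher and 1, Rsad2 (-0.96, SE 0.29), lower, and 0 when adjusted over the list alone (camera adjusted p = 0.194, median -0.43). The integrated stress response had 2 of 16 genes higher and 2 lower (4 and 5 when adjusted over the list alone), with Ddit3 up by 2.04 (SE 0.45), Atf4 up by 1.09 (SE 0.26) and asparagine synthetase Asns at -0.82 (SE 0.20). For this list camera tended downward (adjusted p = 0.924) while the median was 0.05 and the mean 0.22. The 17 genes named in this and the preceding lists of signalling, stress and glycolysis genes reached edgeR adjusted p of up to 0.0976, 0.172, 0.146 and 0.169 without library 7 and controls 1, 2 and 3, where none passed. Without library 4, 5 or 6, 3, 3 and 9 of them were lost (up to 0.0595, 0.0644 and 0.0901), and without any library of the Pkd1 line 4 were lost (up to 0.0674).

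Transcripts of nephron progenitors were present in libraries 6 and 7, where ureteric genes were lower, and the lists of kidney cell types split these libraries from libraries 2, 4 and 5. Nephron progenitor markers had a median of 7.18 and 6.79 in libraries 6 and 7 and at most 0.81 in the other 12, with Osr1 at 203 and 143 CPM and Eya1 at 106 and 108 CPM. Of 9 such markers, Six2 alone was called higher and 0 lower over all genes, and 7 were higher when adjusted over the list alone (camera adjusted p = 0.294, median 4.92). Of 9 nascent nephron markers, Wnt4 was higher (3.65, SE 0.97) and Nphs1 lower (-1.06, SE 0.34), also when adjusted over the list alone (camera adjusted p = 0.802, median 1.63). With library 2 alone these genes had log2 fold changes of -0.90 and 0.08. Of 14 stromal markers, 0 were called, over all genes or over the list alone (camera adjusted p = 0.698, median 0.76). Their medians were 2.12 and 2.02 in libraries 6 and 7, near those of Pkd1 KO 2 (1.80) and Cep120-line control 2 (1.64). Meis2 had 157 and 127 CPM in libraries 6 and 7 against at most 9.34 CPM elsewhere (3.86, SE 1.33, edgeR adjusted p = 0.0638, and called without library 2 at 4.16).

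Ureteric bud tip markers had 0 of 17 genes called (camera adjusted p = 0.0718, median -0.27), with Slco4c1 at -0.75 (SE 0.29, edgeR adjusted p = 0.0875; called without library 2 at -0.92). Their medians were -1.50 and -0.77 in libraries 6 and 7 and -0.16 to 0.25 in the other 12. The list passed, downward, without library 4 (0.0295) or 5 (0.0243), without both (0.0052), with both summed (0.0276), with no low-count filter (0.0287) and with length and GC offsets (0.00426). Trunk and collecting duct markers had 0 of 22 higher and 1 lower, Elf5 (-1.27, SE 0.39), and 0 when adjusted over the list alone (camera adjusted p = 0.194, median -0.11). That list also passed, downward, without library 4 (0.04) or 5 (0.0243), without both (8.97e-05), with both summed (0.0326) and with the offsets (0.0346). Ureteric lineage and epithelial identity had 1 of 16 higher, Pax2 (1.44, SE 0.41; -0.05 with library 2 alone), 0 lower, and 0 when adjusted over the list alone; camera tended downward (adjusted p = 0.924) while the median was 0.07 and the mean 0.19. Pax2 was higher in libraries 6 and 7 than in each of the other 12. With camera the list passed upward without libraries 6 and 7 (adjusted p = 0.00575) and downward without libraries 4 and 5 (0.0125). Nephron progenitor markers passed upward in the latter fit (0.0121).

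Blood and immune markers were lower in libraries 2, 4 and 5 labelled Cep120 KO, and within the range of the controls in libraries 6 and 7. The 11 erythroid markers had 0 called over all genes or over the list alone, with a median of -3.18 (camera adjusted p = 0.000986; adjusted p = 0.424 with an estimated correlation; fry 0.125). The list medians were -7.40, -3.99, -3.79, -0.96 and -1.36 in libraries 2, 4, 5, 6 and 7 and -2.21 to 1.70 in the 3 controls. In the Pkd1 line they ran from -5.98 to 1.01, which takes in libraries 4 and 5, and without library 2 camera gave 0.0608. Of 12 macrophage and leukocyte markers, 0 were higher and 2 lower, with the same counts when adjusted over the list alone (camera adjusted p = 0.0026, median -1.29; adjusted p = 0.424 with an estimated correlation; fry 0.0933; 0.0931 with camera without library 2). The lower genes were Tyrobp (-2.74, SE 0.74) and Fcer1g (-2.47, SE 0.53). The macrophage medians were -2.39, -2.47, -1.78, -0.05 and -0.16 in libraries 2, 4, 5, 6 and 7, -1.13 to 0.52 in the controls and -3.75 to -1.20 in the Pkd1 line, so the Cep120-line controls stood high. Fcer1g had 8.55 CPM in these controls, 0.883 CPM in the Pkd1-line controls and 1.52 CPM in the libraries labelled Cep120 KO (means). Endothelial markers had 0 of 11 called, over all genes or over the list alone, with a camera tendency downward (adjusted p = 0.943) against a median of 0.97 and a mean of 0.85. Egfl7 was at -0.81 (SE 0.37, edgeR adjusted p = 0.145), and with library 2 alone, its spread taken from the other groups, the list passed downward (0.000607). Of 6 neural and neural crest markers, Ncam1 was higher (2.38, SE 0.58; -0.59 with library 2 alone) and 0 lower, also when adjusted over the list alone (camera adjusted p = 0.498, median 1.14). The 8 called genes named from these lists of cell types reached edgeR adjusted p of up to 0.0949, 0.282, 0.135 and 0.143 without library 7 and controls 1, 2 and 3, where none passed. They reached up to 0.0828, 0.0829 and 0.0887 without library 4, 5 or 6, and up to 0.072 without any library of the Pkd1 line.

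**Figure D4:**
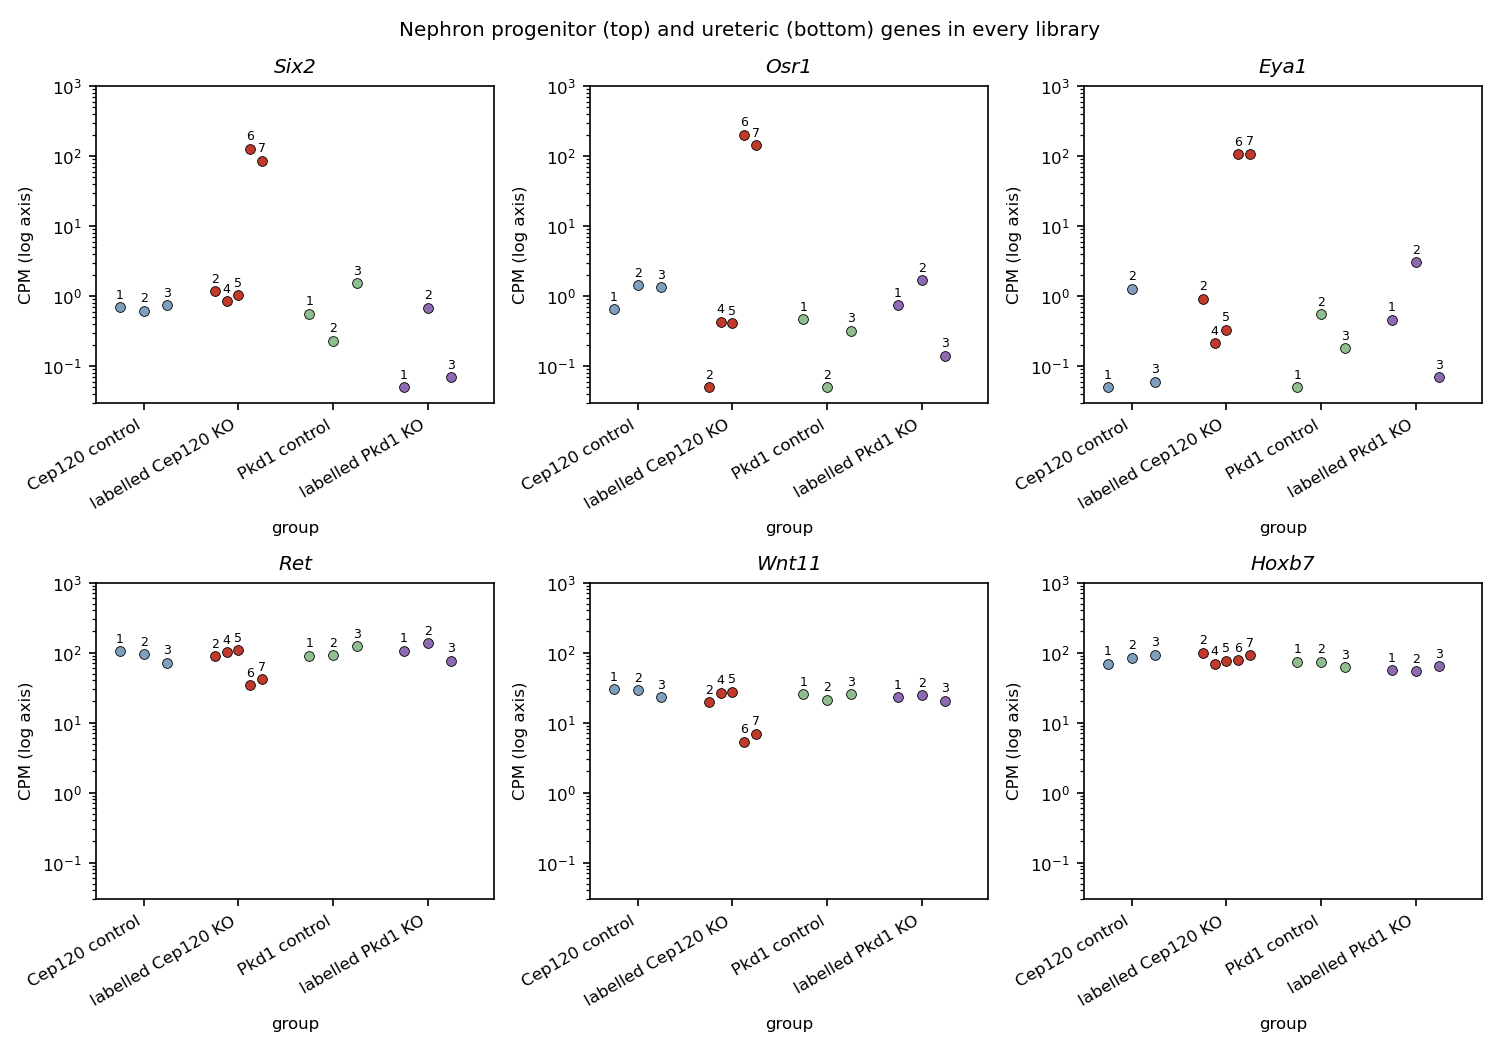
CPM values, on log axes, of 3 nephron progenitor genes (top) and 3 ureteric genes (bottom) in each library by group, with replicate numbers; values under 0.05 CPM are drawn at 0.05. Six2, Osr1 and Eya1 lie at 86.1 to 203 CPM in libraries 6 and 7 of the group labelled Cep120 KO, where Ret (34.5 and 41.2 CPM) and Wnt11 (5.34 and 6.94 CPM) are lower than in the other 12 and Hoxb7 (77.4 and 91.3 CPM) is not.

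No gene was called between the libraries labelled Pkd1 KO and their controls. In simulated counts this comparison recovered 9% of genes changed 2-fold and 75% of those changed 4-fold, so smaller changes could be missed. Neural and neural crest markers were lower, with 0 of 6 called and a median of -1.20 (camera adjusted p = 0.0178; adjusted p = 0.999 with an estimated correlation). Among them the neuronal gene Stmn2 had the smallest p, at 0.812 ± 1.01 CPM (SD, n = 3) against 11.1 ± 17.4 (n = 3). Controls 1, 2 and 3 had 1.31, 31.2 and 0.68 CPM of it, so control 2 carries that mean. Endothelial markers were higher, with 0 of 11 called and a median of 1.05 (camera adjusted p = 0.0497; adjusted p = 0.999 with an estimated correlation). Among them the cadherin gene Cdh5 had the smallest p, at 1.34 ± 1.21 CPM (n = 3) against 0.166 ± 0.159 (n = 3). Cystic kidney disease genes had a median of -0.10 and primary cilium components of -0.01, with 0 called in each, over all genes or adjusted over the list alone. The edgeR quasi-likelihood test called 0 of 16876 genes, with 259 at an unadjusted p under 0.05. A separate fit called 3, DESeq2 3, limma-voom 1, limma-trend 0 (259 unadjusted) and the fit with all 6 controls pooled 0 (326 unadjusted). Among those genes, chosen after their values were seen, the chromatin gene Hmga1 was called by the separate fit (log2 fold change -1.54), DESeq2 (-1.54) and limma-voom (-1.62), and the others were the pseudogenes Rnps1-ps, Atp6v0c-ps2, Gm15725 and Rpl35a-ps4, whose reads are uncertain. All KO libraries lay on the same side of all controls for 11.1% of genes, where chance gives 10%.

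The remaining 24 lists did not pass in Pkd1 KO (camera adjusted p from 0.135 upward), and fry passed 0 lists. Camera tended upward for mitotic surveillance, apoptosis and Hedgehog genes while their medians were -0.02, -0.03 and -0.09, and for interferon-stimulated genes while their mean was -0.02. The neural list missed 0.05 without KO 1 (0.15), KO 2 (0.0878) or control 2 (0.828) and with no low-count filter (0.402). The endothelial list missed it without KO 1 (0.588), KO 2 (0.183), control 1 (0.749) or control 2 (0.127). It also missed it without library 4, 5 or 6 labelled Cep120 KO or control 3 of that line (0.0629, 0.0654, 0.0574 and 0.0593), with DESeq2 size factors (0.0553), no filter (0.333) and the offsets (0.0714). Without KO 3, stromal, macrophage and nephron progenitor markers passed upward (3.04e-05, 5.44e-05 and 0.00473), and without control 3 likewise (0.0248, 3.88e-06 and 0.0232); erythroid markers passed downward without control 1 (0.0345).

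Whether the effect labelled Cep120 KO differs from that labelled Pkd1 KO was tested as an interaction. Lists of p53 targets, immediate early genes, Hippo/YAP targets, centriole components, cystic disease genes, cilium components and mitosis genes were higher in the effect labelled Cep120 KO than in that of Pkd1 KO, and macrophage, glycolysis and erythroid lists lower. Camera passed 10 of 26 lists, led by immediate early and heat shock genes (adjusted p = 2.47e-08, median difference 2.90) and p53 target genes (adjusted p = 8.9e-07, median 1.19). None passed with an estimated correlation (smallest adjusted p = 0.18 with an estimated correlation), and fry passed 7. Plk2 had the smallest adjusted p of all genes (log2 difference 3.15, SE 0.46, adjusted p = 0.122 with edgeR). The edgeR quasi-likelihood test called 0 genes, with 3436 at an unadjusted p under 0.05, while DESeq2 called 715, limma-voom 4383 and the edgeR fit without library 2 called 3140. Without Pkd1-line control 1 the edgeR fit called 1 gene, Plk2 (3.43), and without Cep120-line control 2 it called 1, the pseudogene Gm16042, both seen only after the fits. Of the list calls, mitosis was lost without control 3 of the Cep120 line (0.0647) or Pkd1 KO 2 (0.106), and erythroid markers without library 2 (0.181), control 2 (0.0765) or Pkd1 KO 2 (0.0544). With library 2 alone, its spread taken from the other groups, camera lost mitosis (0.676), cilium (0.676), cystic (0.273) and Hippo/YAP (0.192) lists, and centriole components tended downward (0.144). Without libraries 4 and 5 it lost mitosis (0.0944), cilium (0.0944), cystic (0.0798) and erythroid (0.0944) lists. Mitosis (0.101), centriole (0.125), glycolysis (0.0896), erythroid (0.435) and macrophage (0.172) lists did not pass fry. Lists not called over all libraries passed camera when 1 was left out: DNA replication without library 2, control 1, Pkd1 KO 1 or Pkd1 control 3 (0.0121, 0.0322, 0.0454 and 0.0483). So did mitotic surveillance without library 7, control 3 or Pkd1 control 1 (0.024, 0.0354 and 0.0404). Neural markers also passed without library 2, control 2, Pkd1 control 1 or Pkd1 control 3 (0.0355, 0.0212, 0.017 and 0.0252) and trunk markers without library 5 (0.0385). No gene was called in both comparisons, since Pkd1 KO had 0 calls, so the overlap could not be tested. Across 10204 genes with a mean CPM of at least 5, fold changes of the 2 comparisons had a Spearman correlation of -0.225; genes are not independent replicates.

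The control groups of the lines were compared as a background. Tagap, a gene of activated T cells, was at 10.6 ± 2.85 CPM in Cep120-line controls (SD, n = 3) against 0.185 ± 0.0839 in Pkd1-line controls (n = 3; log2 difference 5.80, SE 0.52, edgeR quasi-likelihood adjusted p = 0.000126). Wdfy1 was higher by 3.97 (SE 0.46, adjusted p = 0.00123 with edgeR) and the histone gene H2ac12 by 9.23 (SE 0.98, adjusted p = 0.000661 with edgeR; near-identical family, uncertain), and the Mediator gene Med1 was lower (-2.06, SE 0.32, adjusted p = 0.0157 with edgeR). The test called 21 genes, 18 higher and 3 lower in the Cep120 line, with 825 at an unadjusted p under 0.05; 11 are pseudogenes. All 8 Cep120-line libraries, the 5 labelled KO included, lay apart from all 6 Pkd1-line libraries in 16 of the 21; the control groups did not overlap in 21.5% of all genes tested, where chance gives 10%. The count was 13, 12, 13 and 12 without Cep120-line control 3 and Pkd1-line controls 1, 2 and 3, and Med1 was lost without these (0.0594, 0.0785, 0.0621 and 0.0892) or Cep120-line control 1 (0.066). DESeq2 called 84, limma-voom 131 and a separate fit 139. Macrophage markers were higher (camera adjusted p = 3.29e-11, median 2.58; adjusted p = 0.227 with an estimated correlation) and neural markers lower (camera adjusted p = 0.0328, median -1.13; adjusted p = 0.583 with an estimated correlation).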

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

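The tests of library sets, of length and GC offsets and of other cells were chosen only after the results were seen, and the counts of other splits were planned.

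Library 2 of the group labelled Cep120 KO stood apart from libraries 4 to 7 in 10 single genes and 3 list medians. Its CPM values, each beside the nearest of the other 4, were 40.1 and 80.3 for Plk2, 3.61 and 12.4 for Pkd1, 125 and 254 for Top2a, 5.97 and 20.5 for Bbs4, and 3.61 and 7.52 for Tctn1. It was higher than the other 4 in Cycs (509 and 246), Rfc4 (220 and 146), Ldha (2300 and 1280), Nphs1 (37.2 and 12.9) and the histone gene H2ac7 (23.5 and 6.78). Its list medians were -0.20 against 0.91 for centriole and centrosome components, 0.11 against 0.89 for cystic kidney disease genes and 0.64 against 2.36 for immediate early and heat shock genes. Its long-minus-short transcript difference was 0.01. Library 6 stood apart in the integrated stress response (-0.53 against 0.08). For 5 independent libraries with normally distributed values, a gap this wide relative to the range arises in about 1 in 20 values. Of 105 values tested, 15 had one, against 5.2 at that rate. Many of these values belong to genes chosen because they were called in this comparison. Libraries 4 and 5 differed by only 3.13 times sampling noise and may not be independent. The 5.2 is therefore no measure of chance here.

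In a test of the difference between the effect labelled Cep120 KO and that of Pkd1 KO, camera passed 10 lists at its preset correlation and 0 with an estimated correlation. Upward were immediate early and heat shock genes (camera adjusted p = 2.47e-08), p53 target genes (8.9e-07), Hippo/YAP targets (7.82e-05), centriole components (0.00382), cystic disease genes (0.0082), cilium components (0.0168) and mitosis genes (0.0215). Downward were macrophage (0.00126), glycolysis (0.00268) and erythroid (0.014) lists. Chance was not excluded for the lists: of 100 labellings within the lines, the real labelling included, 12 gave as many, the highest other 13. The genes cannot test it, since 0 were called and all 100 labellings must give at least that (highest other 1).

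The first pattern is the set of genes called between the libraries labelled Cep120 KO and their controls. Length and GC trends of single libraries do not account for all of it, since 1329 of the 2475 genes stayed called with offsets for them, and neither do other cells in libraries 6 and 7, since 776 stayed called without these. The splits could not exclude chance: 3 of 56 splits of the 8 Cep120-line libraries, the real split included, called as many genes. The others called 5300 and 4986 genes, which points to a structure of the samples. The first set libraries 5, 6 and 7 against libraries 2 and 4 and all controls. The second set libraries 4, 6 and 7 against libraries 2 and 5 and all controls. Both kept most of libraries 4 to 7 apart from every control, so 3 of 56 does not measure a chance rate. Splits placing libraries 4 to 7 with control 1, 2 or 3 called 1647, 1985 and 0. Over the 5716 tested genes called without library 2 and scored against the Pkd1-line controls, library 2 showed -19.1% of the change of libraries 4 to 7, the Pkd1 KO libraries at most 0.7% and the Cep120-line controls, which took part in the choice of genes, -30.6 to -24%. A candidate explanation for a large part of the calls is therefore a difference between library sets, libraries 4 to 7 against the other 10. The labelled genotype stays open beside it, as libraries 4 to 7 belong to 1 group. These libraries were not alike throughout. Over all genes tested, libraries 4 and 5 had Spearman correlations of 0.9 to 0.913 with libraries 6 and 7. With the other 10 libraries they had 0.941 to 0.957, so a single set does not describe them fully.

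The second pattern is the rise of p53 target genes. Length and GC trends were argued against, since the list passed camera with offsets for them (adjusted p = 7.93e-07). A difference between library sets cannot be told apart from the labelled genotype for this list: the median of library 2 was 0.53, above the highest of the 9 libraries of other groups (0.29), but only 1 library labelled KO lies outside libraries 4 to 7. A response to the labelled genotype may contribute, as a hypothesis, and so may the library set. Of 56 splits, the real split included, 8 called as many lists as the 12 seen, the highest other 13, so chance was not excluded for the number of lists.

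The third pattern is the high level of nephron progenitor markers in libraries 6 and 7. The difference shared by libraries 4 to 7 was argued against, since the higher list median of libraries 4 and 5 was -0.04 and lay within the other 10, whose highest was 0.81. Cells of another type in the sort are a candidate explanation. Of 55 genes of the 3 ureteric lists, 34 were lower in both libraries than in each of the other 12. Libraries that vary alike would give 0.6, but libraries 6 and 7 were picked after the values were seen. The share over all genes was not computed, so 0.6 does not measure chance here. Of 9 progenitor markers, 7 were at least 10-fold above each of the other 12. Osr1 and Six2, among the most abundant of these markers, reached 203 and 127 CPM. Of the ureteric lists, 4 genes (Hsd11b2, Pax2, Pax8 and Spry1) were higher in both libraries than in each of the other 12. The cells were sorted for GFP, which should remove such cells, and a change of the sorted cells themselves was not tested.

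For Pkd1 KO, the 10 splits are too few for a share under 0.05: the real split called 0 genes, which all 10 of 10 must reach (highest other 0), and 2 lists (9 of 10, highest other 6). For the control groups the 10 splits are likewise too few, with 21 genes in the real split (1 of 10) and at most 0 in the others.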

How the results depend on the processing

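Fits with library 2 alone, without libraries 6 and 7, without libraries 4 and 5, with these summed and with length and GC offsets were chosen after the data were seen; the other alternatives were planned. With each library left out in turn, genes called for the libraries labelled Cep120 KO ranged from 2 to 5719, their lists from 10 to 13, and the Cep120 log2 fold change from 0.64 to 0.99. The ranges were, for Pkd1 KO genes 0 to 0, Pkd1 KO lists 0 to 5, the Pkd1 log2 fold change in Pkd1 KO -0.76 to -0.52, interaction genes 0 to 3140, interaction lists 8 to 12, control-group genes 12 to 29 and shared calls 0 to 0. With DESeq2 the counts were 4199 (Cep120 KO), 3 (Pkd1 KO), 715 (interaction), 84 (controls) and 1 (shared calls), with limma-voom 6665, 1, 4383 and 131 in the first 4, and with separate fits 0, 3 and 139 for Cep120 KO, Pkd1 KO and the controls. The Cep120 log2 fold change passed with DESeq2 (0.80), limma-voom (1.27) and limma-trend (1.16), and was 0.47 with offsets, 0.51 without libraries 4 and 5 and -0.14 with library 2 alone (edgeR adjusted p = 0.24, 0.263 and 0.906). With no low-count filter the interaction called 1 gene and Pkd1 KO 0 lists, with DESeq2 size factors Pkd1 KO had 1 list, and with offsets 1 list and Cep120 KO 1488 genes. With camera and an estimated correlation, 0 lists passed for Cep120 KO, 0 for Pkd1 KO and 0 for the interaction, and with fry 0 for Pkd1 KO. Cep120 KO and interaction genes numbered 5 and 5 with library 2 alone and 1028 and 4 without libraries 6 and 7; the interaction had 1 without libraries 4 and 5, and Cep120 KO had 1400 with these summed. With library 2 alone, log2 fold changes turned in Pkd1 (-0.30), Mki67 (-0.78), Ccp110 (-0.36), Kif3a (-0.25), Pax2 (-0.048), Myc (-0.066), Egr1 (-0.15), Wnt4 (-0.90), Nphs1 (0.078) and Ncam1 (-0.59), none of which passed. So did the DNA replication list (camera adjusted p = 0.00226, interaction 0.0276) and the centriole list (0.0354); library 2 alone has no spread and is assumed to vary like the other groups. Without libraries 6 and 7, the ureteric lineage list turned upward (0.00575) and nephron progenitor markers turned downward in the interaction (0.0114). Fits with fewer libraries test with fewer samples; for the other changes the cause was not tested. Within 1.5 times the 2475 genes for Cep120 KO were DESeq2 size factors (2460), no filter (2235), limma-trend (3194), pooled controls (3711), gene classes left out (2241) and the fit without libraries 4 and 5 (2065). Limma-trend on the deposited log2 CPM called 2638 higher and 556 lower, against 1418 and 1057, and its median over all genes was 0.45 against 0.12. Of the 66 named genes called for Cep120 KO, Pkd1 among them, 66 stayed called with DESeq2, 64 with its size factors, 58 with limma-voom, 47 with offsets and 0 with the separate fit. With the replicate number as a block, Pkd1 KO had 1 gene (Hmga1, chosen after its values were seen) and 2 lists, nephron progenitor markers (0.0228) among them and endothelial markers not (0.108), and the controls had 120 genes. Pairing by number was checked on the deviations of each library from the mean of its group, gene by gene. These deviations correlated at -0.045, -0.029 and -0.124 between same-numbered libraries of the Pkd1 line and at 0.052, 0.029 and -0.007 between the controls. They therefore showed no pairing by number. For Cep120 KO against its controls, no paired analysis was possible because the libraries labelled Cep120 KO and these controls share only the number 2. Depth limits Pkd1, with 29 to 98 reads per Pkd1-line library.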

Other observations

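All groups and genes below, and their tests, were chosen only after the values were seen.

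Genes for protein synthesis and respiration were lower in the libraries labelled Cep120 KO than in their controls, and collagen genes higher, mainly in libraries 4 to 7. Of 78 cytoplasmic ribosomal protein genes, 69 were called lower and 0 higher (median log2 fold change -0.93; camera adjusted p = 2.23e-38; adjusted p = 0.149 with an estimated correlation). Of 91 nuclear-encoded respiratory complex genes, 51 were lower (median -0.85; camera adjusted p = 1.67e-26; adjusted p = 0.149 with an estimated correlation), and of 13 mitochondrially encoded genes, 8 (median -0.91; camera adjusted p = 1.82e-08; adjusted p = 0.156 with an estimated correlation). Proteasome genes had 15 of 38 lower and 1 higher (median -0.48; camera adjusted p = 1.9e-09; adjusted p = 0.149 with an estimated correlation). Cholesterol synthesis genes had 2 of 19 lower (median -0.36; camera adjusted p = 0.0013; adjusted p = 0.369 with an estimated correlation; median -0.13 without libraries 6 and 7), and replication-dependent histone genes 1 of 50 (median -0.49; camera adjusted p = 0.00106; adjusted p = 0.404 with an estimated correlation). Of 28 collagen genes, 7 were higher (median 1.12; camera adjusted p = 0.0013; adjusted p = 0.38 with an estimated correlation). Their medians were 1.73 and 2.05 in libraries 6 and 7, which also held the progenitor transcripts, and 0.60 and 1.15 in libraries 4 and 5, and the median fold change was 0.44 without libraries 6 and 7. These are 7 families, adjusted together, and ribosomal protein and histone reads are uncertain because of near-identical copies. The ribosomal median was -0.17 in library 2 and -1.04 to -1.33 in libraries 4 to 7, whose short transcripts were lower as a class. In the Pkd1 line it ran from -0.46 to -0.18, so library 2 was not below that line. The respiratory median was -0.22 in library 2 and -0.45 to -0.16 in the Pkd1 line. With length and GC offsets the medians of mitochondrially encoded, ribosomal, respiratory, proteasome, cholesterol, histone and collagen genes were -0.55, -0.78, -0.62, -0.40, -0.47, -0.69 and 0.87. The histone median was -0.12 without libraries 4 and 5. With library 2 alone the medians of collagen, histone and cholesterol genes turned to -1.41, 0.28 and 0.07. None of the 7 turned with DESeq2 size factors or pooled controls. With limma-trend cholesterol, proteasome and histone genes were at -0.03, -0.20 and -0.22 while the median of all genes was 0.45, against 0.12 with edgeR. Limma-voom gave -1.41, -1.04, -0.80, -0.65, -0.23, -1.16 and 1.03 for mitochondrially encoded, ribosomal, respiratory, proteasome, cholesterol, histone and collagen genes.

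In library 2, which lacked the length shift of libraries 4 to 7, p53 target genes were also higher than in other groups. Of the 30, 17 (56.7%) lay above all 9 libraries of the other groups, against 13.8% of all genes tested, where chance gives 10%, and 1 lay below all 9. The p53-induced receptor gene Eda2r had 10.3 CPM against at most 1.62, the cyclin gene Ccng1 65.0 against 30.3, the death-promoting gene Bbc3 3.41 against 1.60 and Btg2 172 against 106. The rise was not particular to p53: 7 of 16 immediate early and heat shock genes (43.8%) and 10 of 25 DNA replication genes lay above all 9. Below all 9 lay 13 of 19 glycolysis gene records, 7 of 11 erythroid markers and 10 of 24 centriole components, against 14.3% of all genes. This is 1 library, so no spread is known for it.

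Cldn4, a tight junction gene of the collecting duct, varied widely between libraries, also within the group labelled Cep120 KO. It had 877, 851 and 1067 CPM in the Cep120-line controls and 98.5 to 212 CPM in the Pkd1 line, a log2 difference between controls of 2.87 (SE 0.87) that did not pass edgeR's test (adjusted p = 0.611). Libraries 2, 4 and 5 had 1336, 1882 and 1856 CPM, and libraries 6 and 7 had 152 and 94.6.

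Differences from the mean of the Cep120-line controls were also compared by chromosome. Their median over X chromosome genes, relative to all 10177 genes compared, was -0.21, -0.23, -0.54 and -0.51 on the log2 scale in libraries 4, 5, 6 and 7. Autosomes moved too: in libraries 6 and 7 chromosome 5 was at 0.23 and 0.18, and chromosome 6 at -0.20 and -0.22. In library 2 the lowest chromosome median was -0.06 and the highest 0.04.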
